A study of Homo sapiens with 3 samples.

How the data were processed

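RNA from the human lung adenocarcinoma line PC-9 was measured in 3 libraries, 1 per condition: wild type cells, cells with the long noncoding RNA LINC00312 knocked down, and cells overexpressing it. Per the labels' protocols, the knockdown used siRNA delivered with a lipid reagent and was harvested 48 h after transfection, whereas overexpression used a lentiviral vector and a stable line selected on puromycin at 2 µg/ml. Cells grew with 10% serum and were collected at 90% confluence. Poly(A) RNA with an integrity number of at least 7 was made into stranded libraries and read as 125 or 150 bp pairs, per the labels' protocols. The protocols also mention a negative-control lentivirus, and whether the wild type library came from untreated parental cells or from cells carrying that control is not stated in the sources used here. No library is labelled as mock-transfected or empty-vector, and the method of delivery differed between knockdown and overexpression together with LINC00312.

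The submitters' processing notes name Bowtie2, TopHat, Cufflinks, HTSeq and the genome build GRCh38. Their versions, their order and the strand setting used in counting are not given in the sources used here. The authors deposited 3 tables, 1 for each pair of libraries, each with 19974 genes, of which 19973 are typed as protein-coding. In the table of overexpression against wild type, the deposited level of a gene is a whole read count. In the other 2 tables the deposited level is a signal, the count divided by a size factor of that pair, per the file headers and the values. Every such value was a whole multiple of 1 step within a tolerance of 1e-06, and the size factors were 1.006 for wild type and 0.9941 for knockdown in their shared table. The authors also gave FPKM values per library, a log2 ratio of each pair, and a p-value and adjusted p-value per gene, per the file headers. The model behind those p-values is not given in the sources used here, and each compares 1 library with 1 library.

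No row of the tables carried LINC00312, so its level was not analysed here and the labels of the knockdown and overexpression libraries could not be checked against it. Mitochondrially encoded transcripts and non-polyadenylated RNAs were likewise not analysed here. Because GENCODE 29 and the submitters' build are both GRCh38, positions of named genes are given on that build.

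Ratios were computed as log2((level + 1)/(level + 1)) within the table of each pair, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. With 1 library per condition there is no spread between replicates and no test was run. A gene was counted as higher or lower when its ratio reached 2-fold and its level was at least 100 in the higher library. The 95% intervals of ratios came from exact Clopper-Pearson limits on the read counts, and they cover counting error only. In 100 simulations of counting error alone, no gene passed the 2-fold rule for either perturbation against wild type, and at most 1 did for overexpression against knockdown.

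A set of 41 gene lists was fixed before the data were examined. Members with a mean level of at least 20 were used, and the median log2 ratio of a list was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list was called above or below when its median lay outside percentiles 2.5 to 97.5, and its 95% interval is an order-statistic interval over members. The minimum of 3 measured members for such a call was set after the data were examined, which left 33 lists. By chance 1.65 of 33 lists would be called if list members varied independently. Members of a list can vary together and lists share members, so more calls could arise without an effect of the condition. These percentiles describe the libraries and are not replicate tests.

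Named genes followed a rule fixed beforehand: in each comparison the 12 genes with the highest and the 12 with the lowest ratio past the 2-fold rule, up to 4 members of each called list and 2 of each other list, LMCD1 and YBX1, and the genes past 2-fold in both perturbations. A few genes that the rule takes in are not reported here. Genes with near-identical copies (PSG5, CES1, IFITM1, HSPA1B, MT1F, MT1X, the keratins, the SPRR, SAA, AKR1C and HLA genes) can share reads with relatives, and their levels are uncertain to that extent. The steps were tested on simulated data. For knockdown against wild type, with 10301 genes in the step, 27 of 50 genes changed 2-fold, 49 of 50 changed 3-fold and 50 of 50 changed 4-fold were recovered. For overexpression against wild type, with 10257 genes, the same 3 sizes gave 27, 50 and 50 of 50, and for overexpression against knockdown, with 10296 genes, 23, 50 and 50 of 50. No unchanged gene was called, but the simulated libraries held counting error alone. They leave out differences between separate cultures, so this does not give the rate of false calls in these data.

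The alternatives comprised 4 other scalings between libraries, other floors, pseudocounts and fold thresholds, the counting interval and the authors' adjusted p-value as added conditions, values from the other tables, and other list settings. FPKM in place of counts, and removal of trends over gene length and GC content, were added after the data were examined. No scaling moved the median log2 ratio of all genes by 0.05 or more.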

Results

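PC-9 is an established line from a human lung adenocarcinoma that carries an activating EGFR mutation. Its messenger RNA was sequenced in 3 single libraries, from wild type cells, from cells with LINC00312 knocked down and from cells overexpressing LINC00312. The study's interest in this long noncoding RNA was its part in migration and vasculogenic mimicry of lung adenocarcinoma, the forming of vessel-like channels by tumour cells, and in its binding to the protein YBX1. The libraries held 15951595 counts for wild type, 15393743 for knockdown and 16034452 for overexpression. Genes with at least 100 counts numbered 10174, 10235 and 10173 in that order. The glycolytic enzyme gene GAPDH was the most abundant transcript in wild type (190535 counts) and overexpression (212874 counts), and the keratin gene KRT8 in knockdown (151602 counts). With 1 library per condition, ratios have no replicate check, and each value compares libraries rather than conditions. Values in parentheses are 95% intervals, from counting error alone for single genes and over members for gene lists, and folds are of (level + 1).

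LINC00312 lies on chromosome 3 at 8571782 to 8574668 (GRCh38, RefSeq), inside the span of the protein-coding gene LMCD1, at 8501823 to 8574668 in the same annotation. Its own level was not analysed here. LMCD1, a LIM-domain gene whose reads may not be separable from those of LINC00312, had 96 counts in wild type, 119 in overexpression and a normalised count of 82.5 in knockdown. The log2 ratios of LMCD1 to wild type were -0.21 (-0.65 to 0.23) in knockdown and 0.31 (-0.09 to 0.71) in overexpression, so neither difference was detectable at this depth. Between overexpression and knockdown the log2 ratio was 0.52 (0.10 to 0.95), higher in overexpression beyond counting error. YBX1, the DNA- and RNA-binding cold-shock protein gene on chromosome 1 at 42682427 to 42702349, differed by -0.43 (-0.47 to -0.38) in knockdown and 0.23 (0.19 to 0.27) in overexpression. Across all genes at the floor the log2 ratios had a standard deviation of 0.41 in knockdown and 0.24 in overexpression. The YBX1 ratios to wild type were each of about that size and so do not stand out from other genes by this measure. Between overexpression and knockdown the YBX1 gap was wider, with normalised counts of 10904 and 6918, and that pair was not set against the spread.

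Knockdown was set against wild type to ask which transcripts differ when LINC00312 is depleted. The serum-responsive transcription factor gene EGR1, on chromosome 5 at 138465490 to 138469315, was 9.78-fold lower in the knockdown library, with a normalised count of 2607 in wild type and 266 in knockdown. Other immediate early and MAPK feedback genes were lower with it, among them PHLDA1 (7.03-fold), the EGFR ligand gene HBEGF (5.97-fold), the ERK phosphatase gene DUSP6 (4.25-fold) and the AP-1 subunit gene FOSL1 (3.98-fold). VTN, which encodes the adhesive glycoprotein vitronectin and lies on chromosome 17 at 28367276 to 28373091, was 75.5-fold higher, with 8.95 in wild type and 750.4 in knockdown. Interferon-stimulated genes and cell-cycle genes were also higher in the knockdown library.

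Of 10399 genes at the floor, 201 were at least 2-fold higher and 83 at least 2-fold lower in knockdown. The 12 lowest ratios also took in the adaptor gene FYB at -2.65 (-3.27 to -2.14), the forkhead factor gene FOXQ1 at -2.30 (-2.62 to -2.01) and the semaphorin and VEGF co-receptor gene NRP2 at -2.26 (-2.86 to -1.77). ALDH3A1, an aldehyde dehydrogenase gene, stood at -1.91, the pseudokinase gene TRIB2 at -1.82, the serine synthesis gene PSAT1 at -1.80 and the ephrin ligand gene EFNB2 at -1.77. After VTN at 6.24 (5.46 to 7.52), the highest ratios were those of VSTM2L at 3.50 (2.73 to 4.65), the collagen gene COL15A1 at 3.40 (2.78 to 4.22) and the small heat shock protein gene CRYAB at 3.14 (2.70 to 3.67). They were followed by the orphan receptor gene GPR176 at 2.71, the interferon-inducible chemokine gene CXCL10 at 2.64, SUSD2 at 2.58, the kisspeptin gene KISS1 at 2.53, the metalloprotease gene ADAMTS9 at 2.51, RASSF2 at 2.42, KRT17 at 2.37 and PSG5 at 2.30.

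Of the 33 lists tested, 9 lay above and 8 below matched random lists in knockdown. Immediate early and MAPK feedback genes had a median log2 ratio of -0.77 (-1.60 to -0.43), lower than all 10000 random lists. Of its 20 measured members, 7 were at least 2-fold lower, none was 2-fold higher, and 19 had a ratio below 0. The interferon response list had a median of 1.01 (0.42 to 1.41), with 11 of 22 members at least 2-fold higher and none 2-fold lower. Among them the antiviral effector genes IFIT1 and RSAD2 stood at 1.52 and 1.72, IFI6 at 1.76 and the interferon beta gene IFNB1 at 2.95, the last from normalised counts of 6.96 and 60.4.

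Proliferation genes were higher by small ratios in many members at once. G2/M and mitosis genes had a median of 0.56 (0.47 to 0.66), with 20 of 21 members above 0 and none at 2-fold, for example the mitotic kinase gene CDK1 (0.92) and the proliferation marker MKI67 (0.78). E2F and S-phase genes had a median of 0.45 (0.31 to 0.67), with the thymidine kinase gene TK1 at 0.75 and the replication licensing gene CDC6 at 0.74. Keratinocyte and squamous genes stood at 0.82 (0.09 to 2.11), with 4 of 11 members 2-fold higher, among them KRT14 (2.11) and the elastase inhibitor gene PI3 (1.06). Hypoxia genes stood at 0.39 (0.04 to 1.15), led by the carbonic anhydrase gene CA9 (2.00) and the prolyl hydroxylase gene EGLN3 (1.98). NF-κB and inflammatory genes had a median of 0.34 (-0.03 to 1.72), with IL6 at 1.72 and SAA2 at 2.00 but the neutrophil chemokine gene CXCL8 at -1.28. Heat shock genes stood at 0.25 (-0.26 to 0.59) and the 3 measured metallothionein genes at 0.77.

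The lists closest to the study's question lay on both sides. Vasculogenic mimicry genes had a median of -0.23 (-0.63 to 0.53), and of 14 measured members the receptor tyrosine kinase gene EPHA2 was 2.62-fold lower, while no member was 2-fold higher. TFPI2 stood at -0.82, the membrane-type matrix metalloprotease gene MMP14 at 0.80 and the endothelial cadherin gene CDH5 at 0.66 (-0.09 to 1.48). Angiogenic factors had a median of -0.44 (-1.24 to -0.02), with 4 members 2-fold lower, including the endothelin gene EDN1 at -1.24, and 2 higher by as much. Matrix proteases and their inhibitors stood at 0.53 (-0.33 to 1.02), with the urokinase receptor gene PLAUR at 1.02, but with no floor on members their median was 0.0916 and lay inside the random range. Mesenchymal genes were inside the random range at 0.19 (-0.43 to 2.07). Their 4 members that were 2-fold higher included SPARC at 2.22, COL5A1 at 2.16 and the fibronectin gene FN1 at 1.63. Fibroblast markers had 2 measured members, COL1A1 at 0.97 and ACTA2 at -0.04, and endothelial markers had CDH5 and ESAM, at 0.74.

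NRF2 targets of the antioxidant response had a median of -0.38 (-0.77 to 0.01), with the cystine transporter gene SLC7A11 at -1.21 and the aldo-keto reductase gene AKR1C1 at -1.15. TGF-β targets stood at -0.30 (-0.63 to 0.47), Hippo and YAP genes at -0.25 (-0.63 to 0.18), both with the matricellular gene CYR61 at -1.15. WNT and Notch genes stood at -0.65 with an interval that included 0, and the Notch target HES1 at -1.16. Housekeeping genes were also below, at -0.26 (-0.32 to 0.12), with GAPDH at -0.45 but the glucuronidase gene GUSB at 0.60. Integrated stress genes were inside the random range at -0.17 (-0.90 to 0.60), but their members were split. Of 20 measured members, 7 were at least 1.5-fold lower, among them the asparagine synthetase gene ASNS at -1.46. Another 6 were at least 1.5-fold higher, among them ATF3 at 1.18. YBX1-related genes lay inside the random range too, with the oncogene MYC at -1.60. Also inside that range were genes of p53 (0.06), lysosome (0.05), epithelial identity (0.05), cholesterol synthesis (0.08), glycolysis (0.10), fatty acid synthesis (-0.22), antigen presentation (0.16), adhesion (-0.10), EGFR ligands and receptors (-0.08), RNA interference (-0.01), ribosomal proteins (-0.17), histones (0.00) and a set of kidney-line markers (-0.09). Of 12 measured members of the EGFR list, 3 were at least 2-fold lower and none was 2-fold higher. These were the ligand genes HBEGF (-2.58), EREG (-1.52) and AREG (-1.37, from normalised counts of 95.4 and 36.2). Markers of lung lineage, neuroendocrine cells and leukocytes had 1 measured member each, FOXA1 at -0.50, ENO2 at 0.69 and CD68 at 0.42.

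The authors' deposited table of this pair listed 91 genes at an adjusted p under 0.05, 62 of them higher and 29 lower, the smallest being 7.25e-27 for VTN. Requiring the counting interval to lie beyond 2-fold left 115 higher and 41 lower genes. Restricting the WNT and Notch list to members at 100 or more turned its median to 0.054, and the angiogenic list then lay inside the random range at -0.19. With no floor on members NF-κB genes lay inside it at 0.26, and with the mean in place of the median so did heat shock genes (0.16), TGF-β targets (-0.14) and housekeeping genes (-0.10).

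**Figure D1:**
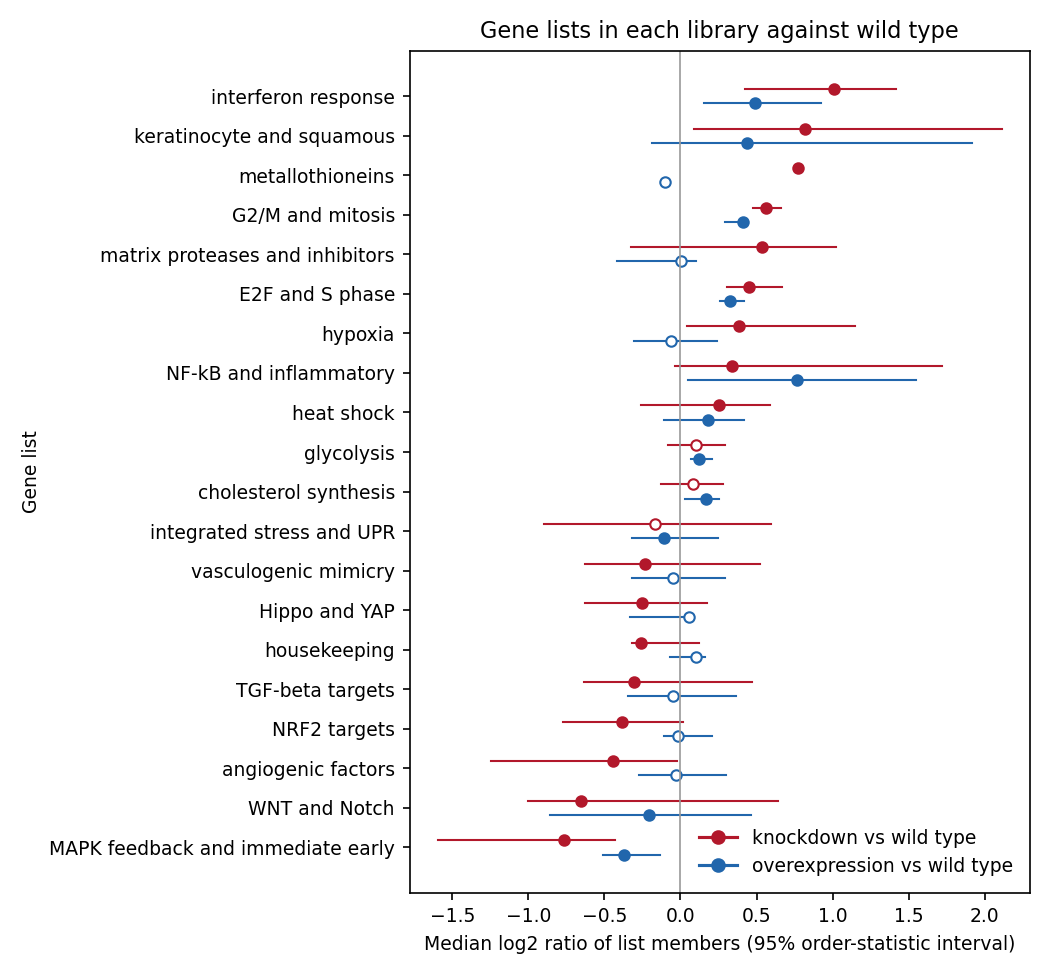
Median log2 ratio to wild type (horizontal axis) of each gene list called in at least 1 of the perturbations, in knockdown (red) and overexpression (blue), with 95% order-statistic intervals over members and open circles for medians inside the random range. The interferon list stood at 1.01 and 0.49, and the immediate early and MAPK feedback list at -0.77 and -0.37; metallothioneins had too few members for an interval.

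Overexpression was set against wild type to ask which transcripts differ when LINC00312 is raised, and fewer genes passed the same rule. EGR1 was again among the lowest, at 4.83-fold lower with 2622 counts in wild type and 542 in overexpression, together with the AP-1 gene FOS at 3.39-fold lower. The liver-type carboxylesterase gene CES1, on chromosome 16 at 55802851 to 55833337, was 5.61-fold lower, from 100 counts to 17. Cornified envelope genes SPRR1A and SPRR3 were 4.25-fold and 3.77-fold higher, and the inflammatory cytokine genes IL6 and IL11 were 3.74-fold and 2.71-fold higher.

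Of 10289 genes at the floor, 20 were at least 2-fold higher and 16 at least 2-fold lower in overexpression. The authors' FPKM values in place of counts, an alternative added after the data were examined, gave 78 higher and 40 lower genes, against 269 and 124 for knockdown. That alternative used a floor of 1 FPKM and a smaller added constant, so its counts and the main counts have unlike thresholds. The highest ratios after SPRR1A at 2.09 (1.47 to 2.86) and SPRR3 at 1.91 (1.44 to 2.46) included IGFN1 at 1.91, IL6 at 1.90 (1.31 to 2.63), the chemokine gene CCL22 at 1.87, the proteoglycan gene SPOCK1 at 1.77 and KRT17 at 1.71 (1.40 to 2.06). They further included NAV3 at 1.61, IL11 at 1.44, TRIM54 at 1.30, the histone deacetylase gene HDAC9 at 1.30 and the actin-binding gene TAGLN at 1.29. The lowest were CES1 at -2.49 (-3.39 to -1.81), EGR1 at -2.27 (-2.41 to -2.14) and FOS at -1.76 (-2.05 to -1.50), then LIPK at -1.58, the matricellular gene CTGF at -1.41, the stress-response gene NUPR1 at -1.34, FAM78A at -1.32 and the glutamate transporter gene SLC1A6 at -1.31. IGFBP5, which binds insulin-like growth factors, stood at -1.22, SPEN at -1.18, the pyruvate dehydrogenase kinase gene PDK4 at -1.16 and YPEL2 at -1.16.

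In overexpression 8 lists lay above and 3 below matched random lists. The interferon list had a median of 0.49 (0.16 to 0.93), with 3 of 21 members 2-fold higher, among them the oligoadenylate synthetase-like gene OASL at 1.13 and IFI44 at 1.17, and with IFIT1 at 0.97. The NF-κB list stood at 0.77 (0.05 to 1.55), where IL6, IL1A (1.85), IL1B (1.55) and SAA2 (1.35) were the members with the largest ratios and all but IL6 had fewer than 50 counts. Keratinocyte genes stood at 0.44 (-0.19 to 1.91), with 4 of 11 members 2-fold higher, KRT6A at 1.11 among them. G2/M genes stood at 0.41 (0.30 to 0.44) and all 21 measured members had ratios above 0, for example CDC20 (0.67) and CCNB1 (0.59), with none at 2-fold. E2F and S-phase genes stood at 0.33 (0.26 to 0.42), with CDC6 at 0.63 and TK1 at 0.52. Cholesterol synthesis genes (0.17, with MVK at 0.43 and IDI1 at 0.41), heat shock genes (0.18, with HSP90AA1 at 0.51) and glycolysis genes (0.12, with LDHA at 0.40) were above by smaller amounts.

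Immediate early and MAPK feedback genes were below, at -0.37 (-0.51 to -0.14), with 2 of 20 members 2-fold lower, EGR1 and FOS, and the phosphatase genes DUSP5 and DUSP6 at -0.97 and -0.91. Integrated stress genes (-0.11, -0.32 to 0.24, with DDIT4 at -0.56 and ATF3 at 0.95) and WNT and Notch genes (-0.21, -0.86 to 0.47, with HES1 at -0.55) were also below, though their intervals included 0. Vasculogenic mimicry genes (-0.05), angiogenic factors (-0.03), mesenchymal genes (0.06) and epithelial genes (-0.04) were inside the random range. Within them the laminin gene LAMA3 stood at 0.68, the fibronectin gene FN1 at 0.61 and the epithelial factor gene ELF3 at -0.49. FN1 was higher by more in the knockdown library, at 1.63. Inside the range too were hypoxia (-0.06), TGF-β (-0.05), Hippo (0.05), NRF2 (-0.01), YBX1-related (0.09) and EGFR family genes (0.09).

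The authors' deposited table of this pair listed 44 genes at an adjusted p under 0.05, 26 higher and 18 lower, the smallest being 1.52e-27 for EGR1. With the floor at 500 counts in place of 100, 1 higher and 1 lower gene passed the 2-fold rule, and the NF-κB list restricted to members at 100 or more lay inside the random range at 0.10. WNT and Notch genes lay inside it with members at 100 or more (-0.0598), with no floor on members (-0.0153) and with the mean (-0.17). With the mean, integrated stress genes (-0.0231) and heat shock genes (0.13) lay inside it too.

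Overexpression and knockdown were also set directly against each other, which leaves the wild type library out. VTN was 28-fold lower in overexpression than in knockdown, and PSG5 and the matricellular gene SPARC were 9.49-fold and 6.64-fold lower. PHLDA1, HBEGF and FOSL1 were 5.09-fold, 4.54-fold and 4.47-fold higher in overexpression, as were the EGFR ligand genes AREG (3.77-fold) and EREG (3.67-fold). The ephrin ligand gene EFNB2 and the receptor gene EPHA2, a member of the vasculogenic mimicry list, were 4.05-fold and 2.62-fold higher in overexpression. Against wild type, the log2 ratios of EFNB2 and EPHA2 were 0.25 and -0.005 in overexpression and -1.77 and -1.39 in knockdown. The gap of both genes thus came mostly from a lower level in the knockdown library. PHLDA1 and HBEGF were below wild type in overexpression too, with 1587 and 233 counts against 2198 and 307.

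Of 10404 genes at the floor, 79 were at least 2-fold higher in overexpression and 213 at least 2-fold lower. Lower genes further included THEMIS2 at -2.75 (-3.68 to -2.06), SUSD2 at -2.69, IGFBP5 at -2.66 (-2.99 to -2.36), VSTM2L at -2.62, COL15A1 at -2.59, SLC45A1 at -2.55, CRYAB at -2.46, the myeloid receptor gene TREM1 at -2.46 and CA9 at -2.45. Higher genes further included FYB at 2.42 (1.90 to 3.04), the deiodinase gene DIO2 at 2.02 (1.89 to 2.16), NRP2 at 1.94, the stanniocalcin gene STC2 at 1.69, FOXQ1 at 1.59 and ALDH3A1 at 1.57.

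In this pair 8 lists lay above and 6 below. Immediate early and MAPK feedback genes were above at 0.52 (0.07 to 1.02), with 6 of 20 members 2-fold higher, and NRF2 targets at 0.39 (0.15 to 0.68), with SLC7A11 at 1.39. Angiogenic factors (0.35, with CXCL8 at 2.05 from 21 and 91 counts), vasculogenic mimicry genes (0.28), Hippo genes (0.30, with ANKRD1 at 1.02), fatty acid synthesis (0.33, with the desaturase gene SCD at 0.94), YBX1-related genes (0.27, with MYC at 1.17) and integrated stress genes (0.20, with PSAT1 at 1.37) were above with intervals that included 0. Hypoxia genes (-0.51, with EGLN3 at -2.10), matrix proteases (-0.48, with MMP14 at -1.16), interferon genes (-0.39, with IFI6 at -1.52), lysosomal genes (-0.19), G2/M genes (-0.13) and the 3 measured metallothioneins (-0.87) were below, the intervals of hypoxia, protease and lysosomal genes including 0. With no floor on members the protease median was -0.22, inside the random range. So were angiogenic (0.11) and Hippo genes (0.12) with members at 100 or more, and Hippo (0.20) and integrated stress genes (0.16) with the mean. The authors' deposited table of this pair listed 65 genes at an adjusted p under 0.05, 18 higher and 47 lower, the smallest being 6.16e-18 for VTN. With that condition added to the size rule, 14 higher and 47 lower genes were left.

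**Figure D2:**
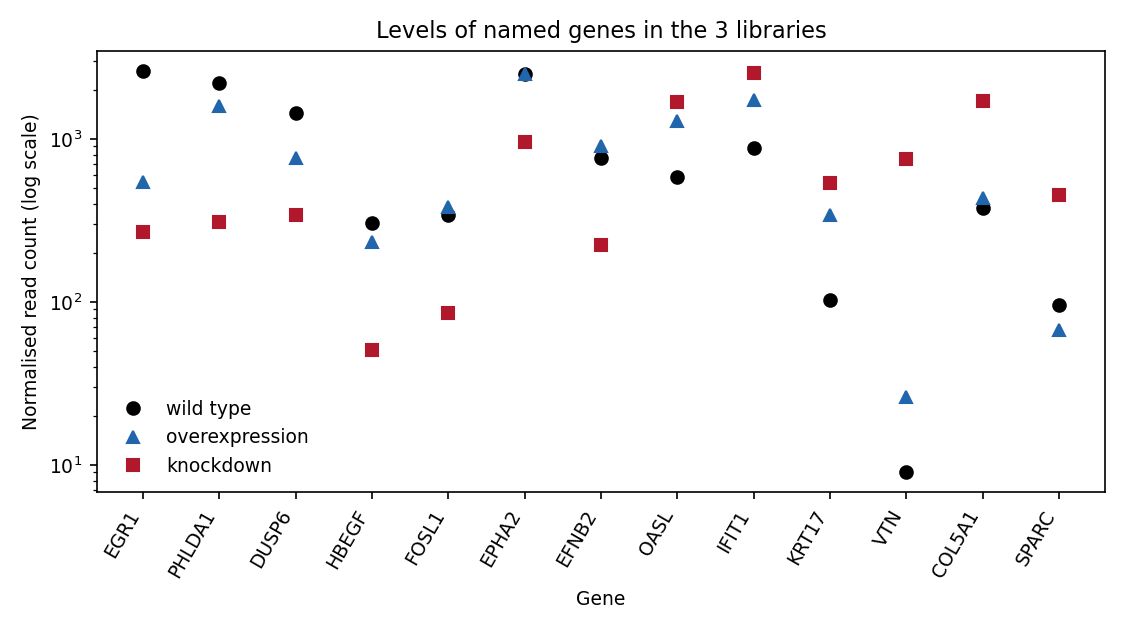
Normalised read counts on a log axis of named genes in wild type (circles), overexpression (triangles) and knockdown (squares), 1 library each. EGR1 stood at 2622 in wild type, 542 in overexpression and 267 in knockdown, and VTN at 9, 26 and 755.

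The perturbations were opposite by design, and genes past 2-fold in both were counted among the 10235 genes at the floor in both pairs. EGR1 and PDK4 were lower in both libraries, and CCL22, IL11, the interferon-stimulated genes ISG20 and OASL, KRT17, SPOCK1 and TAGLN were among 8 genes higher in both, which makes 10 genes with the same direction. IFITM1 (1.30 in knockdown, -1.11 in overexpression), an interferon-induced membrane protein gene on chromosome 11 at 313506 to 315272, and IGFBP5 (1.44 and -1.22), on chromosome 2 at 216672105 to 216695525, were the 2 genes with opposite directions, both higher in knockdown and lower in overexpression. Independent lists would share 0.279 genes in the same and 0.294 in opposite directions, and 100 simulations of counting error alone, with a shared wild type library, gave 0 of either. Across genes, which are not independent replicates, the log2 ratios correlated with a Pearson r of 0.27, against a mean of 0.50 in those simulations. Their covariance was 0.0237 against 0.00443 simulated. The simulations leave out differences between separate cultures, so they do not show what unchanged cultures would give. With a single wild type library, part of the shared direction may come from that library.

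**Figure D3:**
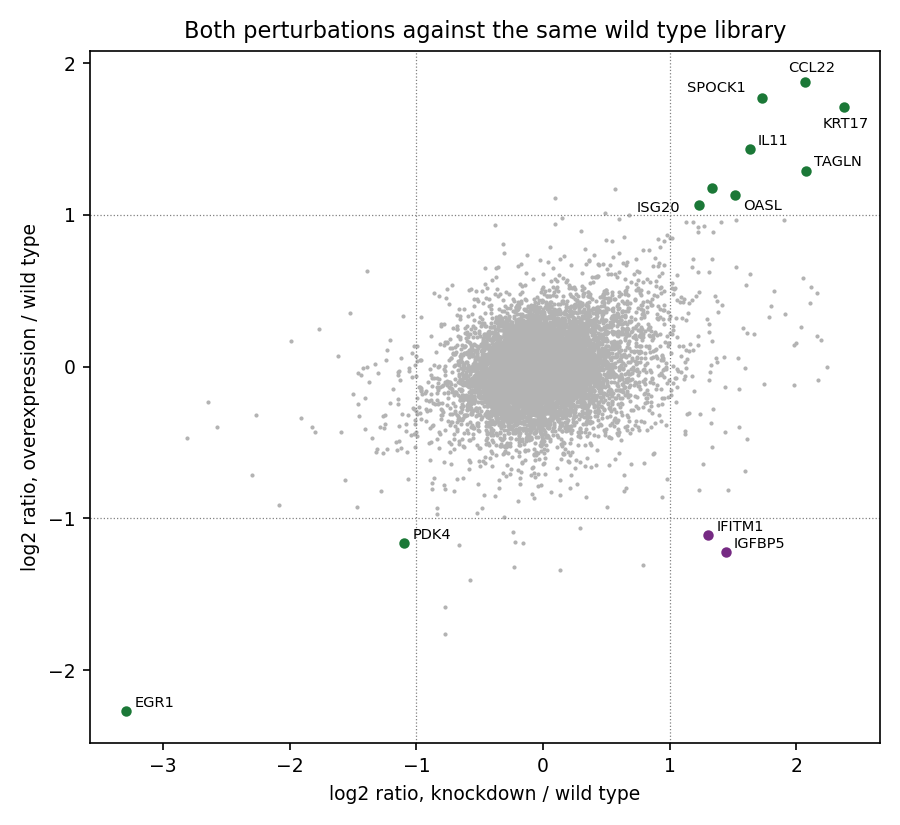
Log2 ratio of overexpression to wild type (vertical axis) against log2 ratio of knockdown to wild type (horizontal axis) for 10235 genes, 1 point per gene, with dotted lines at 2-fold. Coloured points are the 10 genes past 2-fold in the same direction (green) and the 2 in opposite directions (purple), with the genes named in the text labelled.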

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

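FPKM in place of counts and the removal of length and GC trends were chosen after the results were seen; all other alternatives were set before the data were examined. No paired analysis was possible because each condition has 1 library; for the same reason leaving out a replicate and other splits of the samples could not be run, and the level of LINC00312 was not analysed here. Under the 4 other scalings, both other pseudocounts, protein-coding genes alone and values from the other tables, the counts of 2-fold genes stayed within 1.5 times. Of 110 alternative counts, 61 stayed within that range. The cause of the other differences was not tested, except that lower thresholds admit more genes by construction and higher ones fewer.

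In the order knockdown higher and lower, overexpression higher and lower (each against wild type), and overexpression higher and lower against knockdown, the main counts were 201, 83, 20, 16, 79 and 213. With no floor they were 1445, 457, 1492, 639, 890 and 1197, with a floor of 10 they were 548, 210, 285, 114, 317 and 494, and with a floor of 500 they were 79, 45, 1, 1, 36 and 82. The floor of 500 left 2 genes with the same direction in both perturbations and 0 with opposite directions. A 1.5-fold threshold gave 678, 410, 125, 117, 457 and 724, with 79 genes in the same and 15 in opposite directions. A 4-fold threshold gave 28, 7, 1, 2, 6 and 26. Requiring the counting interval beyond 2-fold gave 115, 41, 9, 6, 37 and 103, and adding the authors' adjusted p under 0.05 gave 60, 28, 12, 7, 14 and 47. FPKM values, at a floor of 1 FPKM in place of 100 counts, gave 78 higher and 40 lower genes for overexpression against wild type. They gave 141 higher genes for overexpression against knockdown.

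Called list medians stayed called in 232 of 250 alternative settings, and lists inside the random range became called in 19 of 341. With members at 100 or more, the WNT and Notch median in knockdown turned to 0.0539, and calls ended for angiogenic factors in knockdown (-0.19) and against knockdown (0.11), NF-κB genes in overexpression (0.10), WNT and Notch in overexpression (-0.0598) and Hippo genes against knockdown (0.12); metallothioneins had too few such members. With no list floor, calls ended for matrix proteases in knockdown (0.0916) and against knockdown (-0.22), NF-κB genes in knockdown (0.26) and WNT and Notch genes in overexpression (-0.0153). With the mean in place of the median, calls ended in knockdown for heat shock (0.16), TGF-β (-0.14) and housekeeping genes (-0.10), in overexpression for integrated stress (-0.0231), heat shock (0.13) and WNT and Notch genes (-0.17), and against knockdown for integrated stress (0.16) and Hippo genes (0.20). The interferon, immediate early and MAPK feedback, G2/M, keratinocyte and hypoxia calls were kept in the settings run.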

Other observations

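The tests of pathways, of interferon genes and of immediate early genes, and the removal of length and GC trends, were chosen after results were seen; what would decide each test of the surplus of higher genes was written before its value was known. The authors' deposited tables also assign genes to annotated pathways, and 267 of these had 10 to 200 measured members in knockdown against wild type. Above matched random lists lay 27 of them and below lay 23, where 13.35 would lie outside by chance if members varied independently. Pathway members can vary together and pathways share members, so the excess over that number is not evidence of an effect by itself. Complement and coagulation cascade genes had a median of 0.46 (0.17 to 0.94), with 12 of 26 at least 1.5-fold higher in the knockdown library. Extracellular matrix receptor genes stood at 0.25 (0.06 to 0.35), cell adhesion molecules at 0.24 (0.16 to 0.43), lysosome genes at 0.22 (0.15 to 0.27) and DNA replication genes at 0.29 (0.15 to 0.41). Genes that charge transfer RNAs stood at -0.30 (-0.44 to -0.10), oxidative phosphorylation genes at -0.17 (-0.26 to -0.12) and ribosomal genes at -0.17 (-0.19 to -0.12). The lists fixed beforehand for lysosome (0.05) and adhesion genes (-0.10) lay inside the random range in knockdown, so they do not support the pathway calls on those themes. The ribosomal protein list fixed beforehand (-0.17) also lay inside that range, at percentile 2.55 next to the limit of 2.5.

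In overexpression against wild type, 38 of 268 pathways lay above and 26 below, where 13.4 would lie outside by chance under the same condition of independent members. DNA replication genes had a median of 0.25 (0.18 to 0.30), mismatch repair genes 0.17 (0.06 to 0.30), proteasome genes 0.16 (0.11 to 0.23) and genes of ribosome biogenesis 0.14 (0.10 to 0.21). Ribosome biogenesis genes lay on the other side in knockdown, at -0.18 (-0.22 to -0.08). No member of the proteasome or DNA replication sets reached 1.5-fold in overexpression.

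Interferon response genes were higher in both perturbed libraries than in wild type. A response that follows the dose of LINC00312 would by itself have opposite signs, but the overexpression median of 0.49 had the sign of the knockdown median. A low wild type library stays open, alone or together with a response to dose. Overexpression against knockdown had a median of -0.39 (-0.66 to -0.30), but with 1 library each the spread between cultures is unknown and that value decides nothing here. Delivery of siRNA by lipid or of a lentiviral vector may raise such genes, and 18 of 21 members measured in both pairs were higher in both libraries. This stays open because no library is labelled as mock-transfected or empty-vector, and the sources used here do not state whether the wild type cells were untreated or carried the negative-control lentivirus. An effect of LINC00312 that does not follow its dose also stays untested.

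Immediate early and MAPK feedback genes were lower in both perturbed libraries. A response that follows the dose of LINC00312 would by itself have opposite signs, but the overexpression median of -0.37 had the sign of the knockdown median. Because both medians share 1 wild type library, that library could set the sign, and a part for dose is not excluded. Handling at harvest could act on short-lived transcripts such as EGR1 and FOS. The 12 members outside the immediate early part had a median of -0.99 (-2.09 to -0.44) in knockdown and -0.39 (-0.51 to 0.12) in overexpression. They include MYC, HBEGF, PHLDA1 and FOSL1, which are also early-response transcripts, so this split does not separate handling from the condition in either library, and handling stays open. A wild type library high for these genes also stays open, alone or together with a response to dose. The level of LINC00312 itself was not analysed here, and both readings rest on the labels.

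More genes were higher than lower in the knockdown library, with a ratio of 2.42. Trends over gene length and GC content are a candidate explanation, but after their removal the ratio was 2.80. Over 4 other scalings between libraries the lowest ratio was 2.57, and the 10 most abundant genes took a share of the counts that differed by -0.81 percentage points between knockdown and wild type. None of these accounts for the surplus as a whole. Loss of LINC00312, the transfection itself and a difference between separate cultures, including an unusual wild type or knockdown library, all stay open. With 1 library per condition the design does not separate them.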
